A study of Mus musculus with 8 samples.

How the data were processed

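Total RNA from the adipose fraction of mouse dorsal skin was labelled with Cy3 and hybridised to one-colour Agilent arrays, 1 array for each of 8 samples. The labels name 1 shaved control and 1 sample at each of 7 times after wax plucking, and they give ages of 10 weeks up to 4 d, 11 weeks at 6 d and 10 d, and 17 weeks at 50 d. The labels' treatment protocol gives a younger age at plucking, and the files do not settle the difference.

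Per the file headers, the authors' deposited files hold the intensity of each spot as given by Agilent Feature Extraction, with the background subtracted, spatial and multiplicative detrending switched on, and a surrogate value for dim spots. No normalization between arrays is recorded in the headers. The probes' positions are on the mm9 build per the file headers, and no annotation of that build was used, so exon or UTR positions are not given. Gene names are those of the array design. The accessions of 27229 probes matched a reference gene table of another assembly, GRCm38.p6, which was used for current symbols only.

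Control spots and spots flagged as outliers were left out. Of 55681 probes, 13 were dropped because every spot was flagged on an array, the spots of a probe were averaged, and 55668 probes of 34790 gene names were used. No spot was saturated. Each value is the log2 of the processed signal minus the 75th percentile of its array. The brightest probe over the 8 arrays stood for a gene. At each time a gene was counted when it differed from the shaved control by at least 2-fold and was well above background on the brighter of the 2 arrays. A gene whose probes were all not well above background on the dimmer array has only a bound: its fold was taken against the higher of the lowest signal among probes well above background there and its own signal, and is written as at least N-fold. The counts of genes at each time, the list medians, their percentiles and the differences between windows use the dim array's own value instead, unless dim members are said to be at their bound. The spike-in slope of the 10 d array was outside its range per the file headers.

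The 48 gene lists came from textbook knowledge of skin, fat and plucking, and 10 of their members had no match on the array. A list's median difference was set against 10000 random lists of the same size, matched on mean signal in 20 bins, and it stood apart when its percentile was under 2.5 or over 97.5 and at least 5 members were measured. This describes these arrays and is not a test across mice. Every median of a fixed list against the control that is given before the closing section stood apart in this way. The error of a list median was taken as its bootstrap SD over 1000 draws of its members. Simulated lists of 15 genes were drawn at random from the 1 d comparison, which held 28657 genes. Of 400 lists with no shift 4.75% were called. Of 100 lists shifted by 0.25 on the log2 scale 71% were called, and of 100 shifted by 0.5, 99%. Real lists, whose members can change together, may be called more often by chance.

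The early (12 h, 1 d, 2 d) and late (4 d, 6 d, 10 d) windows were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, over 27818 genes. The arrays of a window served as its 3 samples, so the spread holds true change between times as well as differences between mice. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation. On simulated data for this comparison, 43% of 100 genes changed by log2 1 and 78% of 100 genes changed by log2 2 were recovered. There were 3 false calls among the unchanged of 27818 genes. Genes were simulated independently of each other, and randomly chosen genes got the same change on all 3 late arrays. Real genes that change within a window or together may be recovered less often, so these rates need not hold for them. Other steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

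The genes named were set by a rule. At each time it took the 6 highest and 4 lowest differences measured on both arrays, the 2 largest bounds in each direction, and, for a list described in the text, the 4 members with the largest difference. It also took 10 signalling and fat genes over all times and, for the windows, the 10 leading genes in each direction, by p because none passed. Only genes with a proper symbol were named, and not every gene the rule took is printed. The clock gene levels given across all arrays, the second probe of Siglec1 and the genes named from the test lists of the closing section were chosen after their values were seen. Alternatives were quantile normalization, centring on the median of probes well above background on all arrays, normexp background correction with an offset of 50, a stricter and no filter on background, the mean over probes, the 50 d array as the reference, other fold thresholds, the mean of list members, other window models and leaving out each array. The gene lists, the rule for named genes, the comparisons and all these alternatives were chosen before the data were examined.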

Results

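Gene expression was measured in the adipose fraction of dorsal skin from female C57BL/6 mice, an inbred laboratory strain, after the resting hair coat had been plucked with wax. The labels give 8 samples: 1 from skin that was only shaved, and 1 each at 12 h, 1 d, 2 d, 4 d, 6 d, 10 d and 50 d after plucking. The labels call the material adipose cells, and the series' design text describes tissue around the follicles that includes fat and dermis. Each sample was hybridised to 1 one-colour Cy3 array, all 8 on 1 slide, so no time has a replicate and no difference at a single time carries a test. Between 72.9% and 81.2% of spots per array were well above background. Probes spotted 10 times differed between their spots by a median SD of 0.06 to 0.09 on the log2 scale, and different probes of a gene differed in their change by a median SD of 0.15 to 0.18. These errors are technical, and the spread between mice is unknown. Genes of near-identical families, such as Stfa, Sprr2, Lce, hair keratin, keratin-associated and globin genes, can share hybridisation.

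All 7 comparisons with the shaved control ask how the tissue around resting follicles differed from it over the days after plucking, and all share that single control array. The 4 d array lay farthest from the control, with 1722 genes at least 2-fold higher and 1880 at least 2-fold lower. At 12 h the counts were 1148 and 970, at 1 d 796 and 889, and at 2 d 764 and 1002. At 6 d they were 1247 and 613, at 10 d 1140 and 603, and at 50 d 776 and 1247. Higher genes made up 38.4% of the 50 d calls, and 49.8% with normexp background correction. With normexp the 4 d counts were 1112 and 835 and all 14 counts were smaller. Of 197 values of single genes, 117 moved by more than 0.18 on the log2 scale with normexp and none changed sign. The size of a fold given below therefore depends on the background correction. Pearson's r across genes with the control, over genes that are not independent replicates, ran from 0.969 at 4 d to 0.984 at 1 d and 2 d. Of 336 pairs of a fixed gene list and a time, 217 stood apart, 112 of them as higher. For lists of unrelated genes 16.8 would be expected, but members of a list can change together and all pairs share the control. The number is therefore not a test. A pair of circadian clock genes, picked after their values were seen, separated the control from every plucked array: Arntl, a core activator of the clock, stood at -0.95 there against 1.28 to 2.46, and Dbp, a clock output gene, at 5.45 against 0.81 to 3.46. The fixed clock list had medians of -0.67 at 12 h, -0.80 at 4 d, -0.44 at 6 d, -0.22 at 10 d and -0.38 at 50 d, and did not stand apart at 1 d or 2 d. All these arrays share the control, and the labels give no time of day, so a difference in sampling hour cannot be told apart from plucking for these genes. Some differences from the control given below changed sign when the 50 d array was the reference: Speer2 turned to 0.012 at 12 h, 0.70 at 1 d and 0.34 at 2 d, Rerg to 0.98 at 4 d and 0.39 at 6 d, and Ctse to 0.55 at 1 d. At 12 h, Aif1 turned to 0.36, Irf7 to 0.25 and Il6 to -0.41, and at 10 d Ccnb2 turned to 0.18.

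**Figure D1:**
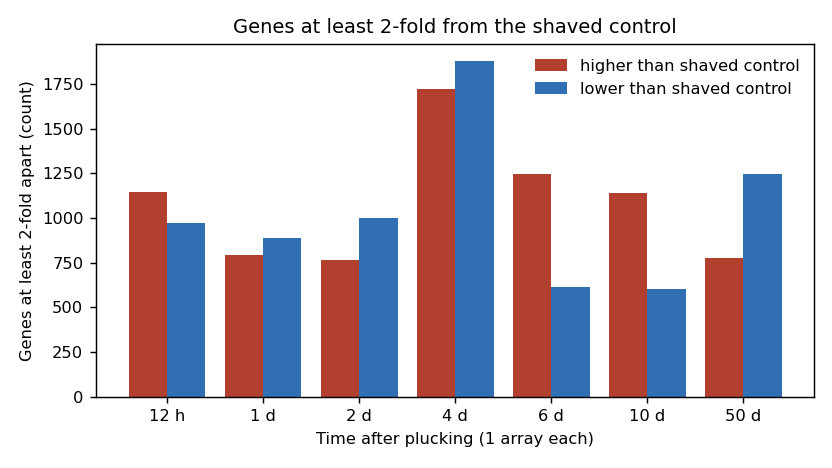
Number of genes at least 2-fold higher (red) or lower (blue) than the shaved control at each time after plucking, 1 array per time, no error bars because no time has a replicate. The 4 d bars are the tallest, at 1722 and 1880 genes.

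At 12 h, genes of keratinocytes, the hair shaft, neutrophils and lymphocytes were above the shaved control. The interfollicular keratinocyte list had a median log2 difference of 1.92, with 16 of 20 measured members at least 2-fold higher, and the hair shaft and inner root sheath list one of 1.53, with 15 of 23. The wound keratinocyte list had a median log2 difference of 4.15, with 11 of 14 measured members at least 2-fold higher. Its cornified envelope genes Sprr2d and Sprr2h were 95.5-fold and 47.0-fold higher, and the stress keratin Krt6b differed by 5.16. Neutrophil markers had a median of 2.19, with 11 of 18 members higher, among them Stfa1 at 297-fold, the alarmins S100a8 at 4.50 and S100a9 at 4.28, and Stfa3 at 4.34. Stfa3 is also in the wound keratinocyte list, and S100a8 and S100a9 are also in the list of alarmins and antimicrobial peptides. Those members are therefore not particular to neutrophils. The B cell list had a median of 3.54, with 7 of 11 members higher, led by Ms4a1, which encodes CD20, at 52.7-fold, Pou2af1 at 4.37 and the B cell receptor chains Cd79a at 4.23 and Cd79b at 4.16. Beside it, the T cell and NK cell list had a median of 0.47, with Cd3d at 4.48 and Lck at 3.20. Glycam1, a mucin of lymph node venules, was at least 1154-fold higher, since it was not well above background in the control. Its probe lies on chromosome 15, 103393339 to 103393398 in mm9. The acute phase gene Saa2 was at least 137-fold higher, the scavenger receptor Marco 60.0-fold and the neutrophil chemokine Cxcl5 43.5-fold. Inflammatory cytokine and acute response genes had a median of 0.85, or 0.47 with a dim member at its bound, with Saa3 at 4.48, Lcn2 at 3.51, Serpina3n at 3.09 and Il1b at 2.60.

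Lower at 12 h were Dbp at -4.64, the protease gene Ctse at -3.76, Speer2 at -3.55 and Frem1 at -3.28. Genes of the G2 and M phases of the cell cycle had a median of -1.20, with 12 of 21 at least 2-fold lower, such as Nusap1 at -1.61 and Cdk1 at -1.42. Macrophage and monocyte markers had a median of -0.89, with Lyz2 at -1.47 and Aif1 at -1.18, and interferon-stimulated genes one of -0.70, with Irf7 at -1.70. Both signs turned when the 50 d array was the reference, at 0.31 and 0.15. Vmn1r104 and Gpc2 were at least 44.1-fold and 29.4-fold lower at 12 h, and both were higher in the control than in each of the other 7 arrays.

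At 1 d, many of the largest differences were in genes of the outer epidermis. The share of epidermis in each sample was not measured, so at no time can it be told apart from a change after plucking for these genes. The interfollicular keratinocyte list had a median of 2.65, with 18 of 20 members at least 2-fold higher, among them Krt1 at 4.45, Lor, which encodes loricrin, at 4.37, Ivl, which encodes involucrin, at 3.61 and Krt77 at 3.52. Cornified layer genes were among the highest: Lce1f was 27.9-fold, Cnfn 25.8-fold, Hrnr 25.4-fold, Flg, which encodes filaggrin, 24.4-fold and Lce1e 22.3-fold higher. The wound keratinocyte median was 1.27, with Sprr1b at 3.84, and Stfa1 was 26.8-fold higher. Glucocorticoid-induced genes had a median of 0.79, with the metallothionein Mt2 at 2.78, Pdk4 at 2.02, Lcn2 at 1.81 and Fkbp5 at 1.79. Pdk4 was lower in the control than on every plucked array, by -1.15 from the lowest of them, so its difference is not particular to 1 d. Ereg, an EGF receptor ligand, was at least 29.3-fold higher. The hair shaft and inner root sheath median was only 0.38, with 1 of 22 members at least 2-fold higher, against 1.53 at 12 h. With the 50 d array as the reference it was -0.75 at 1 d.

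Cell cycle G2/M genes had their lowest median at 1 d, -1.46, with 19 of 21 members at least 2-fold lower, such as Ccnb2 at -1.99 and Kif20a at -1.84. At 50 d it was -0.93, and with the 50 d array as the reference the medians were -0.18 at 12 h and -0.58 at 1 d. Slc6a17 at -3.15, Fam64a, now named Pimreg, at -3.02, Ctse at -2.87 and Speer2 at -2.86 were the lowest measured genes. Macrophage markers had a median of -1.16, with 11 of 18 members lower, and Aif1 at -1.71. Mature adipocyte genes had a median of 0.41 with no member 2-fold apart, and Tshr at 0.84 and the fatty acid transporter Cd36 at 0.75 differed most. Endothelial, mast cell, sebocyte and skeletal muscle markers were higher at 1 d too, at 0.49, 0.52, 0.49 and 0.22. Fibroblast markers were lower, at -0.34. With the 50 d array as the reference the macrophage median was 0.029 and the adipocyte median -0.10.

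At 2 d, hair keratin and epidermal genes were both above the control. The hair shaft and inner root sheath list had a median of 1.84, with 16 of 23 members higher, among them the hair keratin Krt33a at 4.05 and the inner root sheath keratins Krt71 at 4.00, Krt27 at 3.98 and Krt25 at 3.97. Hair keratin-associated genes were among the highest, with Krtap22-2 at 25.6-fold, Krtap9-3 at 19.2-fold and Krtap6-2 at 16.6-fold, and Krtap3-3 was at least 16.9-fold higher. Stfa1 was 46.6-fold and Flg 34.4-fold higher. Melanocyte markers had a median of 0.95, with the melanin synthesis genes Dct at 1.78 and Tyrp1 at 1.69 and the melanosome gene Pmel at 1.71. Interferon-stimulated genes had their lowest median, -1.93, with 15 of 18 members at least 2-fold lower, led by Irf7 at -2.91, Bst2 at -2.45, Oas1a at -2.43 and Oas2 at -2.22. Macrophage markers stood at -1.51, with Aif1 at -2.45 and Fcgr1 at -2.15. The EGF receptor ligand Areg at -3.36, Speer2 at -3.22, the macrophage lectin Siglec1 at -3.22 and Itgb1bp3, now named Nmrk2, at -3.20 were the lowest, and a second Siglec1 probe gave a smaller difference of -1.18.

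At 4 d, genes of the growing hair follicle, pigment cells and dividing cells were all far above the control. Inner root sheath and hair keratins led: Krt25 was 451-fold, Krt35 349.6-fold, Krt28 305-fold, Krt71 279.8-fold and Krt27 239-fold higher, and Tchh, which encodes trichohyalin, 187-fold. The Krt25 probe lies on chromosome 11, 99177867 to 99178575 in mm9. The hair shaft and inner root sheath list had a median of 5.05, with 22 of 23 members higher, and the homeobox gene Dlx2 and the keratin Krt75 were at least 65.5-fold and 56.4-fold higher. Melanocyte markers had a median of 3.98, with Tyrp1 at 5.92, Pmel at 5.67 and Dct at 5.48. Of 24 measured G2/M genes, 22 were at least 2-fold higher with dim members at their bound. Their median was 1.94 at the bound and 2.03 otherwise, with Kif11 at 2.94, Top2a at 2.87 and Mki67 at 2.82, and DNA replication genes had a median of 1.58, with Uhrf1 at 3.29 and Rrm2 at 2.81.

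WNT and follicle progenitor genes also stood high at 4 d. The WNT list had a median of 1.07, with 12 of 24 members higher, among them the nuclear effector Lef1 at 48.1-fold and the secreted WNT inhibitor Wif1 at 22.9-fold. Bulge and hair germ markers had a median of 1.61, with Lhx2 at 4.83, Gli1 at 4.12, Cdh3 at 3.51, and Shh, the hedgehog ligand of the hair germ, at least 23.3-fold higher. Cholesterol synthesis genes had a median of 1.39, with Sqle at 2.66, Cyp51 at 2.15 and Idi1 at 2.09. Mature adipocyte genes had a median of -0.48, with 1 of 18 members 2-fold lower, the glycerol channel gene Aqp7 at -1.03, Adipoq, which encodes adiponectin, at -0.84 and the lipid droplet gene Plin4 at -0.84. Endothelial markers, at -0.33, and fibroblast markers, at -0.42, were lower as well, the latter at 0.20 against the 50 d array. Macrophage markers had a median of -1.65, with 15 of 18 members lower, and interferon-stimulated genes one of -1.69. Macrophage markers were also below the control at 50 d, at -1.24, so their lower values at 2 d and 4 d are not particular to those times. Itgb1bp3 at -5.65, Dbp at -3.72, Speer2 at -3.70 and Rerg at -3.48 were the lowest.

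**Figure D2:**
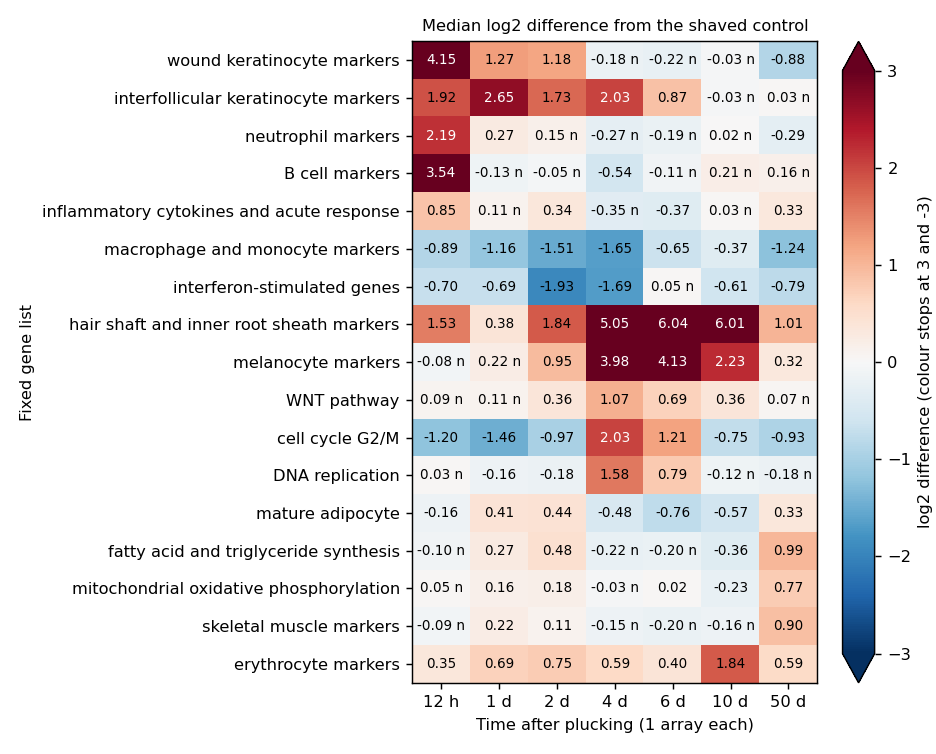
Median log2 difference from the shaved control for 17 fixed gene lists (rows) at the 7 times after plucking (columns), 1 array per time. Red is higher and blue lower, the colour stops at a size of 3, and n marks medians that did not stand apart from random lists. The hair shaft row reads 5.05, 6.04 and 6.01 at 4 d, 6 d and 10 d.

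At 6 d, hair shaft genes were still higher relative to the control and adipocyte genes lower. The hair shaft and inner root sheath median was 6.04, with 22 of 23 members higher, Krt33a at 608-fold, Krt25 at 398-fold, Krt35 at 327-fold, Psors1c2 at 283-fold and Krtap17-1 at 267-fold. Krtap28-13 and Krtap3-3 were at least 461-fold and 303-fold higher. Melanocyte markers stood at 4.13, with Tyrp1 at 5.95 and Pmel at 5.08, G2/M genes at 1.21, with Top2a at 1.72, and WNT genes at 0.69, with Lef1 at 5.01 and Wnt10a at 2.61. Mature adipocyte genes had their lowest median, -0.76, with 3 of 18 members at least 2-fold lower. Its members Cidec at -1.14, Cidea at -1.13 and Adig at -1.01 concern lipid droplets or adipogenesis, and Cebpa, at -0.98, encodes an adipogenic transcription factor. The lipolysis list had a median of -0.41, with the hormone-sensitive lipase gene Lipe at -1.51, and endothelial markers one of -0.30. Rerg at -4.06, Speer2 at -3.68, Peli3 at -3.32 and Veph1 at -2.98 were the lowest.

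At 10 d, hair keratin genes stood far above the control while G2/M genes stood below it. The hair shaft median was 6.01, or 5.55 with dim members at their bound, and Krt33a was 444-fold, Krtap22-2 422-fold, Krtap9-3 299-fold and Krt33b 279-fold higher. Melanocyte markers had a median of 2.23, with Tyrp1 at 3.49. G2/M genes had a median of -0.75, with 8 of 21 members at least 2-fold lower and Ccnb2 at -1.16 and Aurka at -1.11, and against the 50 d array the median was 0.12. DNA replication genes did not stand apart. Erythrocyte markers had a median of 1.84, with 7 of 11 members higher, the haem synthesis gene Alas2 at 2.38 and the globin gene Hbb-b2 at 2.10. Sebocyte markers had a median of -0.64, with Elovl4 at -3.07 and Cidea, also a member of the mature adipocyte list, at -2.29. The wax synthesis gene Far2 was at least 11.4-fold lower. The epidermal genes Flg2 and Lor also lay below all other arrays at 10 d, by -3.26 and -3.23 from the lowest of them. Mature adipocyte genes stood at -0.57, with Cidec at -1.12 and the lipid droplet coat gene Plin1 at -0.87, and fatty acid synthesis genes at -0.36, with the triglyceride synthesis enzyme Dgat2 at -1.44. Itgb1bp3 at -5.71, Cyp2g1 at -4.88 and Defb6 at -4.32 were the lowest, with Dbp at -3.98.

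At 50 d, when the mice were 17 weeks old against 10 weeks for the control, the uncoupling protein gene Ucp1 and lipid synthesis genes stood out. Ucp1, a marker of brown and beige fat, was 343-fold higher, and its probe lies on chromosome 8, 85821788 to 85821847 in mm9. The fructose transporter gene Slc2a5 was 16.1-fold, Cidea 12.6-fold and Arntl 8.25-fold higher. Fatty acid and triglyceride synthesis genes had a median of 0.99, with 8 of 18 members higher, led by Elovl6 at 5.17-fold, Acss2 at 1.97, Acly at 1.86 and Me1 at 1.72. Mitochondrial oxidative phosphorylation genes had a median of 0.77, with none of 25 reaching 2-fold and Ndufs1 the highest at 0.95. Skeletal muscle markers stood beside them at a median of 0.90 and Myh7 at 1.34. Hair shaft genes had a median of 1.01, with Krt28 at 3.04 and Krt35 at 2.99. Macrophage markers stood at -1.24, with 13 of 18 members lower, and fibroblast markers at -0.61, with Col3a1 at -0.95. The kallikrein gene Klk6 at -3.49, Ctse at -3.42, Dbp at -3.36 and Saa3 at -2.85 were the lowest.

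**Figure D3:**
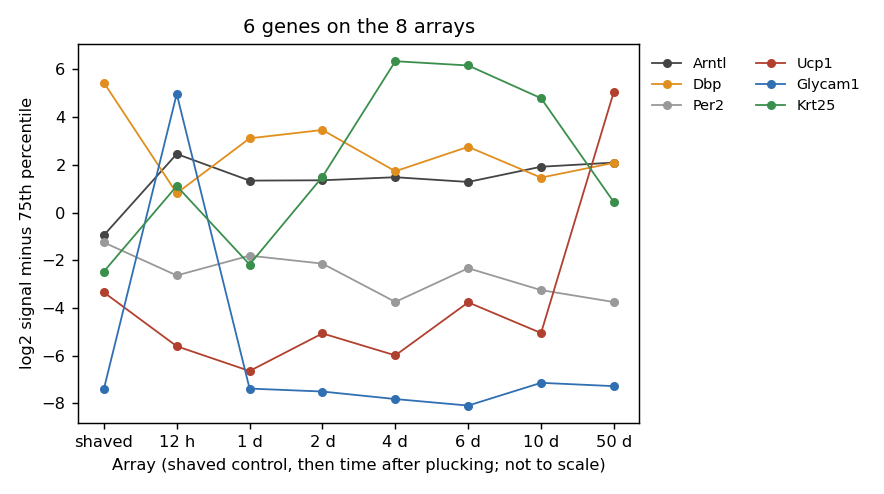
Level of 6 genes on the 8 arrays, as log2 signal minus the 75th percentile of the array (vertical), from the shaved control to 50 d (horizontal, not to scale), 1 point per array, to be read within a gene. Ucp1 stands at 5.08 at 50 d, Glycam1 at 4.97 at 12 h, and Dbp is highest and Arntl lowest in the shaved control.

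Signalling and fat genes were followed over all times. Hair follicle genes were high at 4 d, 6 d and 10 d, so which cells of these samples expressed the signalling genes cannot be told. The monocyte chemokine Ccl2 was 0.73 from the control at 12 h, -0.60 at 1 d, -1.27 at 2 d, -1.45 at 4 d, -0.89 at 6 d, -0.71 at 10 d and -0.44 at 50 d. The cytokine genes Tnf, Il1b and Il6 stood at 1.11, 2.60 and 1.20 at 12 h and at -0.29, -0.39 and 0.11 at 1 d, and at 50 d they were 0.42, 1.64 and 1.61. The ranges that follow give the lowest and the highest value over all times, and not a course in time. Bmp2, known from fat as a signal that holds follicles at rest, ranged from 0.28 at 1 d to 1.18 at 10 d, and Bmp4 from -0.30 at 12 h to 1.11 at 4 d. Wnt5a ranged from -0.97 at 12 h to 0.90 at 4 d, and Fgf7, a dermal growth factor, from -0.58 at 1 d to 0.03 at 10 d. Adipoq ranged from -0.92 at 6 d to 0.56 at 2 d, and the leptin gene Lep from -0.75 at 4 d to 1.08 at 50 d.

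The early window (12 h, 1 d and 2 d) was set against the late window (4 d, 6 d and 10 d) to ask which genes differed across the days around the onset of hair growth. No gene of 27818 passed an adjusted p of 0.05 in limma (smallest adjusted p = 0.0963), and 3372 had an unadjusted p under 0.05. The 10 leading higher values in the late window, by p, each higher on 3 of 3 late arrays than on any early one, were the hair keratin regulator Foxn1 by 3.18 (SE 0.29), Sct by 3.14, Wnt10b by 1.39, Cybrd1 by 3.44, Adamts19 by 2.49, Foxq1 by 1.45, Mt4 by 3.22, Crnn by 4.05, Krt35 by 6.49 and the melanosome receptor gene Gpr143 by 5.26. The 10 leading lower values included the adipocyte genes Cidec at -1.47 and Plin4 at -1.21. The others were Tusc5 at -1.56 (SE 0.12), Vipr1 at -1.28, Pon1 at -1.69, C1qtnf9 at -1.07, Slc22a4 at -1.28, the mucin gene Muc16 at -1.85, Stc2 at -1.42 and Lrrc26 at -1.70. Of these 20 leading genes, 17 were well above background on all 8 arrays. For the rest, a size that rests on a dim array is not exact. Without the 4 d array 130 genes were higher in the late window and 64 in the early one, and without the 10 d array 243 and 64. The windows also lie in different rows of the slide, so row and window cannot be told apart among these 6 arrays.

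Among the fixed lists, limma's camera test with its preset correlation of 0.01 put 33 of 48 past an adjusted p of 0.05. With an estimated correlation no list passed, and the smallest adjusted p was 0.221, that of hair shaft, mature adipocyte, endothelial, melanocyte and WNT genes among others, while G2/M genes had adjusted p = 0.318 with an estimated correlation. The estimates were 0.32 for hair shaft, 0.38 for mature adipocyte, 0.11 for endothelial, 0.41 for melanocyte and 0.99 for G2/M genes. The p-values that follow assume 0.01 and are too small where members vary together more than that. At the preset correlation, hair shaft and inner root sheath genes were higher in the late window, with a median difference of 4.14 (adjusted p = 7.86e-30), and 21 of 23 passed when adjusted over the list alone. G2/M genes were higher by 2.01 (adjusted p = 5.01e-17), with 20 of 21 adjusted over the list alone, and melanocyte genes by 3.16 (adjusted p = 2.22e-10), with 9 of 12, and 1 was lower. Mature adipocyte genes were lower, with a median of -0.85 (adjusted p = 2.16e-12), as were endothelial markers at -0.88 (adjusted p = 1.20e-12), and 11 of 18 and 14 of 17 passed when adjusted over each list alone. Against the control, endothelial markers stood higher in the early window, at 0.52, 0.49 and 0.56 at 12 h, 1 d and 2 d. Mature adipocyte genes stood higher at 1 d and 2 d, at 0.41 and 0.44, but lower at 12 h, at -0.16. These window differences thus hold early higher values as well as late lower ones. Against the 50 d array the endothelial median at 12 h was -0.042. No member of any list passed over all genes tested.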

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

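No paired analysis was possible because each group has 1 sample. The arrays have no replicate, so dim probes and the single control set the limits: 75.3% of spots were well above background on the control. Quantile normalization, median centring and the mean over probes kept all 14 counts of genes apart from the control within 1.5 times, and no list or gene reported turned its sign under them. At a 1.5-fold threshold, in order of time, 2334, 2377, 2183, 3040, 2392, 2571 and 2950 genes higher and 2924, 2232, 2426, 4917, 2354, 1740 and 3549 lower were counted, and at 4-fold 399, 222, 183, 700, 495, 366 and 131 genes higher and 174, 160, 188, 261, 118, 177 and 180 lower, as a looser or stricter threshold must give. With normexp, 548, 424, 335, 1112, 638, 561 and 402 genes higher and 384, 371, 520, 835, 341, 214 and 406 lower were counted, and higher genes made up 49.8% of calls at 50 d against 38.4%. The cause was not tested. Of 197 values of single genes 117 moved under normexp, and none changed sign under normexp, quantile normalization or median centring. With the filter at all 8 arrays, which tests fewer genes, there were 675, 488, 774 and 744 higher at 12 h, 2 d, 6 d and 10 d and 622, 576, 386, 330 and 815 lower at 12 h, 1 d, 6 d, 10 d and 50 d. With no filter, which counts dim genes too, there were 1239 and 1271 higher at 1 d and 50 d and 1493 and 1081 lower at 12 h and 6 d. Against the 50 d array there were 1935 and 1975 higher at 6 d and 10 d and 623, 1211 and 1583 lower at 2 d, 6 d and 10 d, and the cause was not tested.

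Medians that turned sign against the 50 d array, where the cause was not tested, were DNA replication genes at 0.069 and 0.049 (1 d and 2 d), G2/M genes at 0.12 (10 d), endothelial markers at -0.042 (12 h), erythrocyte markers at -0.40, -0.0014, -0.062, -0.027 and -0.045 (12 h, 1 d, 2 d, 4 d and 6 d), lipid synthesis genes at -0.83 and -0.61 (1 d and 2 d) and fibroblast markers at 0.20 (4 d). Others were hair shaft genes at -0.75 (1 d), inflammatory cytokine genes at -0.14 (2 d), interferon-stimulated genes at 0.15, 0.12 and 0.27 (12 h, 1 d and 10 d), macrophage markers at 0.31, 0.029, 0.55 and 0.83 (12 h, 1 d, 6 d and 10 d), mature adipocyte genes at -0.10 (1 d), oxidative phosphorylation genes at -0.63, -0.59 and -0.75 (1 d, 2 d and 6 d) and skeletal muscle markers at -0.53 and -0.76 (1 d and 2 d). Single genes that turned were Aif1 at 0.36 (12 h), Ccnb2 at 0.18 (10 d), Ctse at 0.55 (1 d), Il6 at -0.41 (12 h), Irf7 at 0.25 (12 h), Rerg at 0.98 and 0.39 (4 d and 6 d) and Speer2 at 0.012, 0.70 and 0.34 (12 h, 1 d and 2 d). A further 136 gene values and 66 medians moved against the 50 d array without a change of sign. The values against the 50 d array rest on 1 control array and 1 array at 50 d, of different ages. With the mean of members, 28 list values moved by more than the bootstrap SD. Only 1 turned sign, that of erythrocyte markers at 12 h, at -0.0024. In the same sense 26 list medians moved under normexp, 20 under quantile normalization and 8 under median centring.

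Between the windows, limma gave 0 genes under quantile, median, normexp, probe mean, filter and trend settings. It gave 4 genes higher in the late window and 2 in the early one with the control and 50 d arrays as a further group, and 4 higher in the early window with no moderation of the variance, and the cause was not tested. Leaving out 1 array at a time gave from 0 to 243 genes higher in the late window and from 0 to 64 in the early one: 130 and 64 without the 4 d array, 243 and 64 without the 10 d array, and 0 without each of the others. All 33 lists kept their direction and their side of the threshold under median centring, normexp, the probe mean and both filter settings. With an estimated correlation 0 lists passed. The estimates ran from -0.050 to 0.99 over the lists, so the 33 calls depend on the preset of 0.01. Leaving out 1 array ended 2 calls without 12 h, 1 without 1 d, 4 without 2 d, 3 without 4 d and 8 without 10 d. Interferon-stimulated genes (adjusted p = 0.0394, higher in the late window) missed the threshold with quantile normalization (adjusted p = 0.0582) and turned direction without the 6 d array (adjusted p = 0.837). Leaving out 1 array gave adjusted p from 1.33e-05 without 4 d to 0.951 without 2 d, with 0.144 without 10 d, and the cause was not tested.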

Other observations

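The tests of slide row, dilution, scaling, blood and the splits of the arrays, and the brown fat list, were chosen after the values that prompted or decide them had been seen. The follicle and lymphoid test lists were written before their values were seen, but a run that held 3 genes of each shared with the fixed lists was seen before those were dropped, and that the limit must also hold with dim members at their bound was added after the values were seen.

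Brown fat genes outside the fixed lists were higher at 50 d than in the control. Their median log2 difference was 0.89 (bootstrap SD 0.24, percentile 100), with 4 of 10 members at least 2-fold higher. Skeletal muscle markers, at 0.90, and oxidative phosphorylation genes, at 0.77, were also higher at 50 d, and Cox7a1, Cox8b and Fabp3 of the brown fat list are also expressed in muscle. The list stood apart at 2 d too, at 0.36, and did not at 10 d, at 0.03. The fatty acid transporter Slc27a2, already seen among the leading genes, stood at 2.90, the thyroid hormone deiodinase Dio2 at 2.17 and the mitochondrial subunit gene Cox7a1 at 1.11, while the brown fat lineage genes Zic1 and Lhx8 stood at 0.18 and -0.05. CC chemokines were higher at 12 h, with a median of 0.88, or 0.71 with dim members at their bound, and lower at 4 d, at -1.33, and alarmin genes were higher at 12 h, at 2.17, with the antimicrobial peptide gene Defb14 at least 25.8-fold higher.

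Hair follicle genes were high at 4 d, 6 d and 10 d in samples labelled as adipose. A position effect of the slide row is argued against, because the control lies in the row of these 3 arrays and their lowest hair shaft median above it was 5.05. The follicle test list did not decide whether RNA of growing follicles in the sampled layer was the cause. Its 15, 16 and 17 measured genes outside the fixed lists had medians of 1.11, 0.91 and 0.74, each at percentile 100. The lowest, 0.740 (bootstrap SD 0.79), lay below the 1 set in advance by less than its SD. With the 3 shared genes Padi3, Dsg4 and S100a3 the lowest median was 1.12 (bootstrap SD 1.34), past that limit by less than its SD. Because 15 of the 20 genes first listed were well above background in the control, a median of this list cannot decide the question. Outside the fixed lists, 8, 7 and 8 members were at least 2-fold higher at 4 d, 6 d and 10 d, and 0 were 2-fold lower. Vsig8 stood at 7.81 and Krt82 at 5.03 at 6 d. These higher members and the hair shaft list go with RNA of growing follicles, but the cells they came from were not measured. The inner root sheath keratin gene Krt25 was 451-fold above the control at 4 d, and a change in the fat and dermis themselves after plucking was not tested.

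Mature adipocyte genes were lower than the control at 4 d, 6 d and 10 d. With the control as the baseline, they lay further below it than genes of other cell types at 6 d and 10 d. At 6 d the adipocyte median lay -0.48 (bootstrap SD 0.08) from the pooled median of 70 endothelial, pericyte, fibroblast and muscle genes, and -0.36 (SD 0.08) at 10 d. This cannot decide on dilution by follicle RNA, because follicle tissue may hold RNA of the pooled genes too. Crabp1, for instance, is in both the fibroblast and the dermal papilla list. These SDs are over genes of 1 array and not over mice. At 4 d the gap, -0.23 (SD 0.15), was under 2 SDs. From the early to the late window, endothelial markers were lower by as much as adipocyte genes, with medians of -0.88 and -0.85. Pericyte markers stood at -0.44, muscle markers at -0.27 and fibroblast markers at 0.26. Against the early arrays adipocyte genes were therefore not lower than endothelial genes. Scaling of the arrays is argued against, since the highest adipocyte median at 6 d over 3 other settings was -0.65. A change in fat cells after plucking, the share of other tissues in each sample, and the difference in age may contribute and were not tested.

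B cell genes were high at 12 h. Blood carried into the sample is argued against, because erythrocyte genes stood at 0.35 at 12 h and 1.84 at 10 d, where the B cell median was 0.21 and did not stand apart. Lymphoid tissue in the 12 h sample stays open: 7 measured genes of lymphoid organ stroma outside the fixed lists had a median of 1.06 (bootstrap SD 0.85, percentile 99.98), and 3 were at least 2-fold higher with dim members at their bound, Ch25h at 1.37, Madcam1 at 1.06 and Chst4 at least 6.64-fold. That median passed the limit of 1 by less than its SD and was 0.85, below it, with dim members at their bound. The median was 1.05 with the 3 shared genes Ccl19, Cr2 and Cxcl12. Because 8 of the 11 listed genes on the array were well above background in the control, a median of so few genes cannot decide the question. Glycam1, a mucin of lymph node venules whose value had been seen before, is not in the list. Its level was 4.97 at 12 h and -7.40 in the control, where it was not well above background. An entry of lymphocytes after plucking was not tested.

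The 6 arrays of the windows can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. For single genes limma gave 0 in the real split and at most 0 in the others, and at an unadjusted p under 0.05 it gave 3372 and at most 3341, the latter for 12 h, 4 d and 6 d against the rest. For lists camera gave 33 in the real split and at most 27 in the others.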
